A study of Mus musculus with 3 samples.

How the data were processed

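RNA was measured on 3 Affymetrix mouse expression arrays, 1 per sorted population of the adult mouse spleen: Spic-negative monocytes, Spic-positive monocytes and red pulp macrophages. Per the labels, all cells came from mice with 1 Spic allele carrying a green fluorescent protein (GFP) reporter, so that GFP reports Spic, a transcription factor of red pulp macrophages. Per the series' design text, spleen cells were depleted of CD4, CD8 and B220 bearing cells with magnetic beads. Monocytes were then sorted as positive for CD11b (Itgam) and Ly6C and split by GFP, and macrophages were sorted from spleen cells as high for F4/80 (Adgre1) and for GFP. The design text describes the depletion for the monocytes, while the treatment protocol lists it for all 3 populations, so whether the macrophages were depleted first stays unknown. No step of the sort was directed at erythroid cells. Per the labels' protocols, total RNA was purified on columns and biotin-labelled cRNA was made with a 2-cycle amplification kit.

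The deposited values are log2 expression per probe set, made by the authors with RMA (background correction, quantile normalization and a summary over probes), per the submitters' processing notes. The version of RMA is not given in the sources used here. The scale is not stated either and was taken as log2 from the values, which ran from 1.82 to 14.50. No value was below 0, so genes were not centred. The array medians were 5.01 for Spic-negative monocytes, 5.08 for Spic-positive monocytes and 4.96 for red pulp macrophages. RMA with quantile normalization assumes that the arrays share 1 distribution of intensities, so a difference in total RNA per cell is not visible, and amplification over 2 cycles shortens cRNA and can change the balance between transcripts. Scanner files were not used here.

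The table held 45101 probe sets, of which 64 were controls and were left out of the gene comparisons. Of the other 45037, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were unnamed here. Symbols were updated through the gene identifier for 34741 probe sets, with a gene table of the GRCm38.p6 assembly that served only for names and for membership of the X and Y chromosomes. Probe sets with several symbols named no gene. Each of the 18193 genes was given the log2 value of its probe set with the highest mean over the 3 arrays. A floor was set at log2 5.02, the median of all probe sets other than controls over all arrays, and the 12375 genes whose brightest array lay above it were compared. Levels under the floor are near background, so a fold against them depends on the background.

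Each group had 1 array, so the number of arrays limits the precision, no spread between animals could be estimated and no significance test of a gene or list was run. Differences of log2 values were counted at 2-fold and at 4-fold. For 34 gene lists fixed before the data were examined, the median difference of the members above the floor was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list was called set apart when its percentile was below 2.5 or above 97.5, as a description of these arrays, and 10000 bootstrap draws over members gave a 95% interval. The position of Spic-positive monocytes between the other arrays was their difference from Spic-negative monocytes divided by that of red pulp macrophages, over genes at least 4-fold different between the latter 2. Because the Spic-negative array enters both differences, the values were also computed after exchanging the 2 monocyte arrays at random for each gene, 1000 times. The genes named are, per comparison, the 15 with the largest difference in each direction among genes whose probe sets above the floor all moved the same way, with at most 2 genes from families of near-identical copies, and any member of the fixed lists. A gene that the rule selects among those lower in Spic-positive monocytes is not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

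The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for cyclic loess. It was tested on simulated data with noise of 0.40 log2 (SD) in the difference of 2 arrays. Measured differences had SDs of 0.57 between the monocyte arrays, and of 1.30 and 1.24 for macrophages against Spic-negative and Spic-positive monocytes. How often shifts are found at these wider spreads was not simulated. Of 200 simulated lists of 15 genes, 5.00% were set apart with no shift and 98.0% with a shift of 0.50 log2. Of 200 genes raised by log2 2.00, 99.5% passed 2-fold. Simulated positions of 0, 0.2 and 0.5 came out as 0.018, 0.213 and 0.502. The alternatives were the mean or median of a gene's probe sets, arrays centred on their medians, quantile normalization again, cyclic loess, no floor or a floor at the 75th percentile, no probe sets ending in _x_at or _s_at, thresholds of 1.5-fold and 3-fold, selection at 2-fold and 8-fold or on the second brightest probe set, random lists without matching, and lists without their member of largest difference. An alternative for linear values was not needed.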

Results

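The series profiled 3 cell populations of the mouse spleen on 1 array each: monocytes without Spic, monocytes with Spic, and red pulp macrophages, the resident cells that clear aged red blood cells and recycle their iron. The title of the series places the study in the development of these macrophages from monocytes, and the sort asks how monocytes that express Spic differ from those that do not and from the mature macrophage. There were no replicates, so differences are described by size only, as log2 differences between single arrays. Across 12375 genes the Spic-positive and Spic-negative monocyte arrays correlated with Pearson's r of 0.964, against 0.807 between macrophages and Spic-negative monocytes and 0.817 between macrophages and Spic-positive monocytes. Genes are not independent replicates, and these values only describe the arrays.

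The genes behind the sort are given as a check of the labels. Spic measured log2 5.66 in Spic-negative monocytes, 9.22 in Spic-positive monocytes and 12.23 in red pulp macrophages on its brighter probe set, and 4.64, 9.61 and 11.78 on the other. Itgam (CD11b) measured 8.68, 7.38 and 5.23 in the same order. A probe set shared by Ly6c1 and Ly6c2 measured 12.97, 12.79 and 11.48. Adgre1 (F4/80) measured 10.77, 10.67 and 12.50. Of the genes for the depletion markers, Ptprc, whose B220 isoform was targeted and which all leukocytes express, measured 13.46, 13.58 and 12.88. Cd4 measured 6.70, 6.96 and 6.93, Cd8a 4.76, 5.73 and 6.51, and Cd8b1 lay below the floor on all 3 arrays. As a list, the sort markers were not set apart in any comparison, with medians of 0.20 between the monocyte arrays, 0.98 for macrophages against Spic-negative monocytes and 0.38 for macrophages against Spic-positive monocytes, except that the second was under 1 of 9 alternatives, quantile normalization again.

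Control probe sets differed between the arrays. The 18 hybridization controls, spiked in at a fixed amount, were all brighter on the Spic-positive array than on the Spic-negative array, by a median of log2 2.16, while macrophages and Spic-negative monocytes differed by 0.07. The 8 probe sets for the 3' ends of the poly(A) controls were brighter on the Spic-positive array by a median of 1.24. The 3' minus 5' difference of the Gapdh controls was 0.48 in Spic-negative monocytes, 2.25 in Spic-positive monocytes and 1.61 in macrophages, and that of beta-actin was 0.74, 0.57 and 1.13.

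Of 16 genes typical of red pulp macrophages, 7 were at least 2-fold higher in Spic-positive than in Spic-negative monocytes. Vcam1, an adhesion receptor of red pulp macrophages, was higher by log2 5.58, and the complement genes C1qa, C1qb and C1qc, which encode the chains of C1q, by 4.31, 4.30 and 4.06. The heme-degrading enzyme gene Hmox1 was higher by 1.95 and the iron exporter gene Slc40a1 (ferroportin) by 1.82. Of 29 cytokine and chemokine genes 10 were at least 2-fold higher, and of 9 MHC class II genes 6, among them the chemokine gene Ccl5, at 6.87 in Spic-negative and 11.87 in Spic-positive monocytes, and the MHC class II transactivator Ciita, higher by 1.78. Markers of B cells, which also carry MHC class II, were at least 2-fold higher in 11 of 13 members. Of 15 classical monocyte genes 2 were at least 2-fold lower, among them Vcan, which encodes the proteoglycan versican (-1.56).

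In counts, 432 genes were at least 2-fold higher and 379 at least 2-fold lower in Spic-positive monocytes, so 53.3% of the differing genes were higher. This split was 42.4% after centring the arrays on their medians and 63.1% after cyclic loess, which moved the median difference of all genes from -0.06 to -0.13 and 0.04. At 4-fold, 82 genes were higher and 6 lower.

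**Figure D1:**
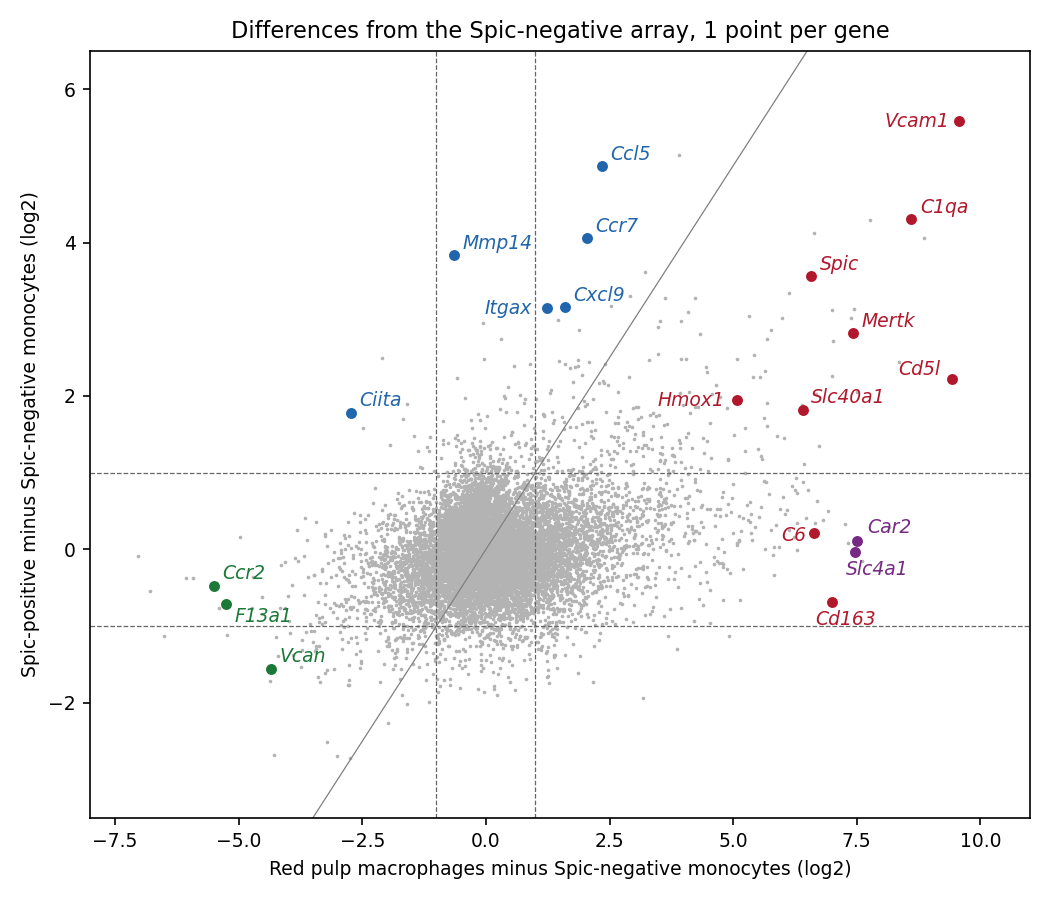
Log2 difference of Spic-positive monocytes (vertical axis) and of red pulp macrophages (horizontal axis) from Spic-negative monocytes, 1 point per gene for 12375 genes, with dashed lines at 2-fold and a solid line where both differences are equal. Vcam1 lay at 5.58 and 9.58, C1qa at 4.31 and 8.61, and Cd163 at -0.68 and 6.99.

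The 15 largest differences upwards under the naming rule were led by Vcam1, Dnase1l3, which encodes an extracellular DNA-digesting enzyme (5.14), and Ccl5. After them came C1qa, C1qb, the guanylate-binding protein gene Gbp8 (4.13), C1qc and Ccr7, the receptor that guides cells to lymphoid tissue (4.05). The matrix metalloprotease gene Mmp14 was higher by 3.83, the protein C receptor gene Procr by 3.61 and Spic itself by 3.56. Marco, a scavenger receptor gene, differed by 3.34, the kinase gene Nuak1 by 3.30, the Rab GTPase gene Rab30 by 3.28 and the immunoglobulin light chain segment Iglv1 by 3.27. Vcam1, Dnase1l3, C1qa, C1qc, Gbp8, Procr, Nuak1 and Rab30 lay below the floor in Spic-negative monocytes.

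Downwards the differences were smaller. The sialyltransferase gene St3gal4 differed by -2.72, the stefin gene Stfa2l1 by -2.69, Dmkn (dermokine) by -2.68, E230016K23Rik by -2.51, the class I-like gene H2-T24 by -2.27 and Rin2, a Rab5 regulator, by -2.02. The other genes named lay between -1.94 and -1.80. These were Igkv9-120, the phosphodiesterase gene Pde7b, Serac1, Ppp1r3b, which directs a phosphatase to glycogen, Zswim1, Lrif1, Lcmt2 and 1810014B01Rik. Stfa2l1, E230016K23Rik, Serac1, Zswim1 and Lcmt2 lay below the floor in Spic-positive monocytes. The direction of Igkv9-120 and 1810014B01Rik turned under 1 alternative each, with 0.49 without probe sets that can bind several transcripts and 0.12 from the median of the gene's probe sets.

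Among 16 red pulp macrophage genes above the floor, 7 were at least 2-fold higher in Spic-positive monocytes and none was 2-fold lower, with a median of 0.86 (95% interval over members 0.35 to 1.88, percentile 100). Mertk and Axl, receptors for the uptake of dying cells, were higher by 2.81 and 1.08, Cd5l, a secreted scavenger receptor family member, by 2.22, and Nr1h3, the liver X receptor alpha, by 1.88. Other genes of this list differed little: the hemoglobin scavenger receptor Cd163 by -0.68, the complement gene C6 by 0.21, the nuclear receptor Pparg by 0.35 and the erythropoietin receptor Epor by -0.45. Cd163 and C6 were below the floor in both monocyte populations and measured 11.48 and 11.22 in macrophages.

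Of 22 heme and iron genes, 3 were 2-fold higher, namely Hmox1, Slc40a1 and the ferroxidase gene Cp (2.37), and 19 differed by less than 2-fold. The median of 0.17 (interval -0.04 to 0.44) lay at percentile 99.7 and was no longer set apart against random lists without matching. Blvrb, a biliverdin reductase, differed by 0.58, the transferrin receptor Tfrc by 0.67, the ferritin heavy chain gene Fth1 by 0.35 and the heme transporter Slc48a1 by -0.07. Targets of the heme and oxidant responsive regulators NRF2 and BACH1 had a median of 0.44 (interval -0.09 to 1.46, percentile 100), with 5 of 13 at least 2-fold higher. Beside Hmox1 and Slc40a1, these were the glutathione synthesis gene Gclm (1.73), the cystine transporter Slc7a11 (1.46) and the thioredoxin reductase gene Txnrd1, at 8.90 and 9.90 in Spic-negative and Spic-positive monocytes. The 7 heme synthesis genes all differed by less than 2-fold (median 0.13, not set apart).

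The list of classical monocyte genes was lower, with a median of -0.47 (interval -0.68 to -0.31, percentile 0.01), although only Vcan and the haptoglobin gene Hp (-1.41) of 15 passed 2-fold. Ccr2, the receptor that brings monocytes out of the bone marrow, differed by -0.47 and F13a1, coagulation factor XIII A, by -0.71, and both stayed above log2 12 in Spic-positive monocytes. Nonclassical monocyte genes had a median of 0.11 (percentile 98.2), with the integrin gene Itgax (CD11c, 3.14) as the 1 of 13 past 2-fold. The call ended under 5 of the 10 alternatives, including the list without Itgax.

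MHC class II genes were higher, with 6 of 9 past 2-fold and a median of 1.20 (interval 0.65 to 1.78, percentile 100). Ciita was joined by the invariant chain gene Cd74 (1.29), H2-Eb1 (1.21) and H2-Oa (1.97). Among 29 cytokine and chemokine genes, 10 were 2-fold higher and 1 lower, with a median of 0.49 (percentile 100). The chemokine genes Cxcl9 and Ccl4 were higher by 3.16 and 2.02 and Il1rn, the interleukin 1 receptor antagonist, by 1.70, and the cytokine gene Il6 differed by -1.02. Interferon-stimulated genes had a median of 0.35 (percentile 100) with 2 of 25 past 2-fold, Gbp2 (1.64) and Ifit2 (1.47). B cell markers moved with these groups: 11 of 13 were at least 2-fold higher, with a median of 1.5 (interval 1.38 to 2.27, percentile 100), including Ms4a1 (CD20, 2.39), Cd22 (2.27) and the complement receptor Cr2 (2.48). Ighm, the IgM heavy chain, was 11.47 in Spic-negative and 12.97 in Spic-positive monocytes.

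Cell cycle genes had a median of 0.52 (interval 0.30 to 0.76, percentile 100), with 6 of 30 past 2-fold, among them Cdk1 (1.65), the spindle checkpoint kinase gene Bub1b (1.66), Top2a (1.29) and the proliferation marker Mki67 (1.02). On the same array 3 alpha-globin probe sets were higher by 4.04 to 5.13, Mpo by 2.86 and Kit by 2.16. Genes for the uptake of apoptotic cells had a median of 0.28 (percentile 99.9), with 4 of 20 higher, namely Mertk, Axl, the phosphatidylserine receptor Timd4 (3.02) and the scavenger receptor Stab2 (2.05), and 2 lower, Pros1 (-1.16) and the integrin gene Itgb3 (-1.54). Immediate early and heat shock genes had a median of 0.23 (percentile 100), with 1 of 22 past 2-fold, Egr3 (1.41).

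Markers of other cell types were also set apart for neutrophils (median 0.22), plasma cells (0.29), erythroid cells (0.38), dendritic cells (0.21), plasmacytoid dendritic cells (0.46), platelets (0.45) and the basophil, mast cell and eosinophil group (0.66). Each of these calls ended under at least 1 alternative, in 8 of 10 for the erythroid list and 6 of 10 for the dendritic list, whose median was -0.018 without Ccr7. T cell (-0.01), NK cell (0.11) and endothelial and stromal markers (0.11) were not set apart. Nor were complement (0.15, set apart under 3 of 10 alternatives), lysosome (-0.04), cholesterol and lipid handling (-0.01), macrophage transcription factors (-0.07), chemokine and chemoattractant receptors (0.13), pattern recognition receptors (-0.24), adhesion (-0.03), oxidative phosphorylation (-0.06), glycolysis (-0.13) and ribosomal proteins (-0.05). Transcription factors, chemokine and chemoattractant receptors and pattern recognition receptors were set apart under 2 of 10 alternatives each. Over all 3 comparisons 57 of 102 list medians were set apart, and these are not independent, since lists share members and comparisons share arrays.

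Where a gene differed by 2-fold, 81.7% of its further probe sets above the floor moved the same way, and at 4-fold 90.7%, but only 33.1% and 74.4% did so by 2-fold. Probe sets of a gene share the RNA, so this covers probe set error and not variation between animals.

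**Figure D2:**
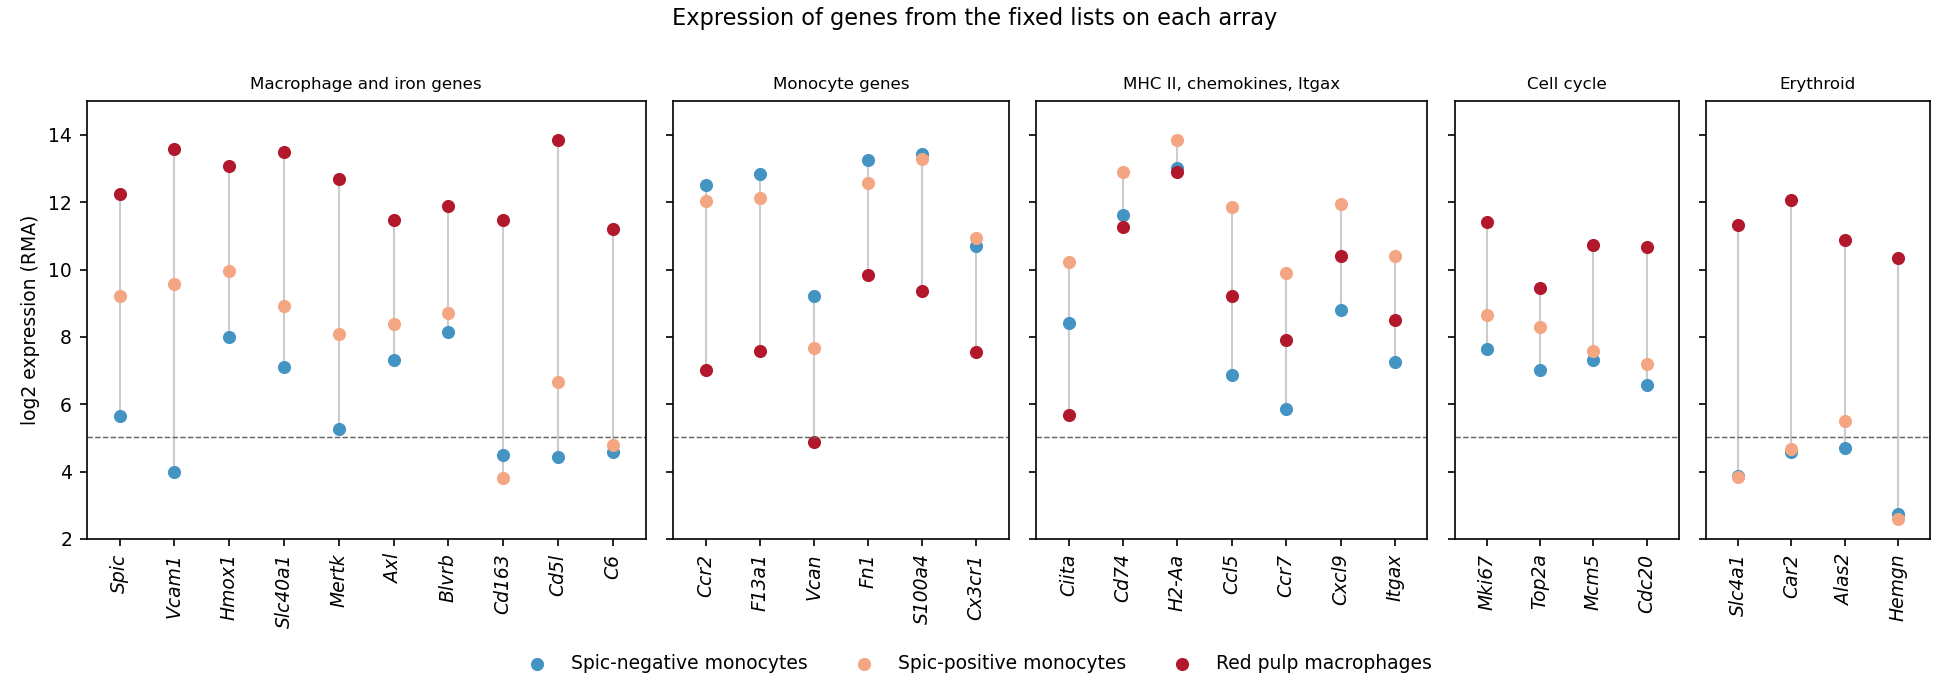
Log2 expression of genes from the fixed lists on each array, 1 dot per array (Spic-negative monocytes blue, Spic-positive monocytes orange, red pulp macrophages red), with grey lines joining the arrays and a dashed line at the floor of 5.02. Hmox1 was 8.01, 9.96 and 13.08 in this order, F13a1 was 12.84, 12.14 and 7.58, and Ciita was 8.43, 10.21 and 5.69.

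Red pulp macrophages had higher levels of macrophage genes and of many iron genes than Spic-negative monocytes. Vcam1 was higher by log2 9.58 and Cd5l by 9.43, C1qc, C1qa and C1qb by 8.85, 8.61 and 7.76, and Mertk by 7.43. Cd163, Slc40a1 and Hmox1 were higher by 6.99, 6.41 and 5.07. The monocyte genes Ccr2 and F13a1 were lower, with differences of -5.50 and -5.26. Erythroid genes were high on the macrophage array, with Car2, a carbonic anhydrase, higher by 7.51 and Slc4a1, the red cell anion exchanger band 3, by 7.46. How far erythroid RNA adds to the iron and heme synthesis genes on this array was not tested.

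At 2-fold, 2421 genes were higher and 1402 lower in macrophages, and at 4-fold 913 were higher and 325 lower. The other named genes upwards were Fcna, a ficolin (8.37), the collagen gene Col14a1 (8.15), the erythroid gene Hemgn (7.60), Stab2 (7.51), the disintegrin protease gene Adamdec1 (7.45), Asb2, a ubiquitin ligase subunit (7.38), and Xist, the RNA of the inactive X chromosome (7.32). Downwards, the interferon-induced gene Ifi44l differed by -7.04, the Y-linked gene Eif2s3y by -6.79, Stxbp6 by -6.50, the DNA-binding interferon-inducible gene Ifi202b by -6.07 and Gdpd3, a lysophospholipase D, by -5.92. The GTPase regulator gene Tiam1 (-5.39), the phospholipase gene Plcb1 (-5.24), BC018473 (-4.98), the Y-linked demethylase gene Kdm5d (-4.73), Ifit1bl1 (-4.72) and AI839979 (-4.53) came next. The anticoagulant receptor thrombomodulin, Thbd, and the matrix protein thrombospondin 1, Thbs1, differed by -4.53 and -4.37. Of the 15 genes with the largest differences upwards, only Fcna, C1qb and Mertk were above the floor in Spic-negative monocytes, and of the 15 downwards, only Ccr2, F13a1, Tiam1, AI839979, Thbd and Thbs1 were above it in macrophages, so the size and order of the other differences rest on background levels. Ifi44l, Ifi202b, Gdpd3 and BC018473 were above log2 8.2 on both monocyte arrays and below the floor in macrophages, and a difference in strain between the mice was not tested. Leaving out the genes of the X and Y chromosomes, an alternative chosen after seeing the data, left 2352 genes higher and 1349 lower.

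All 16 red pulp macrophage genes were at least 2-fold higher, with a median of 5.66 (interval 3.54 to 6.64, percentile 100). Of 22 heme and iron genes, 13 were higher and 2 lower, with a median of 1.64 (percentile 100). The higher ones included Blvra (2.56), Tfrc (4.06), Slc48a1 (1.99) and Ncoa4, the receptor for ferritin turnover (2.14). Lrp1, a receptor for heme bound to hemopexin, and the heme exporter Flvcr1 were lower, with -1.12 and -1.51. Erythroid markers were higher in 12 of 14 members with a median of 4.78 (interval 3.15 to 6.20, percentile 100), among them Alas2, the erythroid enzyme of heme synthesis (6.20), and the erythroid transcription factor Klf1 (4.77). NRF2 and BACH1 targets had a median of 1.15 with 7 of 13 higher, a call that ended with the median of probe sets, and heme synthesis genes a median of 1.08 with 5 of 7 higher, which was not set apart (percentile 97.3) but was under 5 of 10 alternatives.

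Complement genes were higher in 9 of 12 members with a median of 3.43 (percentile 100), including C6 (6.64), the complement receptor Vsig4 (4.80) and properdin, Cfp (3.50). The anaphylatoxin receptor C5ar1 was lower, with -3.22. Cholesterol and lipid genes had a median of 1.20 with 13 of 20 higher, among them the cholesterol exporter Abca1 (3.29), Nr1h3 (3.98) and Fabp4 (4.11). Cell cycle genes were at least 2-fold higher in 29 of 30 members (median 2.57, interval 2.24 to 2.94), with Cdc20 at 4.08 and Mki67 at 3.79, on the array that also carried the erythroid transcripts. Cytokine and chemokine genes had a median of 0.69, with 14 of 29 higher and 7 lower. Igf1 (6.73), Il10 (6.27) and Cxcl1 (5.21) were higher, and Ccl9 and Ccl2 differed by -2.99 and -2.28. Oxidative phosphorylation genes had a median of 0.47 with 2 of 27 past 2-fold, a call that 2 of 10 alternatives ended.

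Classical monocyte genes were 2-fold lower in 12 of 15 members (median -2.11, interval -4.07 to -1.29, percentile 0), with S100a4 at -4.07 and the fibronectin gene Fn1 at -3.41. Nonclassical monocyte genes were lower as a list (median -0.73, percentile 1.11), with the fractalkine receptor Cx3cr1 at -3.14 and Nr4a1 at -2.07 but Fabp4 higher. Interferon-stimulated genes were 2-fold lower in 10 of 25 members and higher in 1 (median -0.67, percentile 0.125), with Oas3 at -3.43 and Oasl2 at -2.63. Chemokine and chemoattractant receptors had a median of -0.69 (percentile 0.24), with 8 of 16 lower and 4 higher, the latter including Ccr3 (6.51) and Cxcr3 (2.51).

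Macrophage transcription factors went both ways, with 9 of 28 higher and 6 lower and a median of -0.31 that was not set apart. Pparg (3.77) and Nr1h3 were higher, and Cebpa, a factor of myeloid precursors, and the heme-binding repressor Bach1 were lower, with -2.88 and -1.42. Pattern recognition receptors were 2-fold higher in 8 and lower in 9 of 26 (median -0.23, not set apart), with Mrc1, the mannose receptor, higher by 6.24 and Msr1 at -2.48. MHC class II genes were not set apart as a list (median 0.21), although Ciita differed by -2.74. Lysosome genes (0.23), apoptotic cell uptake (-0.03), glycolysis (0.31) and ribosomal proteins (-0.12) were not set apart either, although apoptotic cell uptake was under 2 of 10 alternatives. Adhesion genes (0.61) and immediate early and heat shock genes (0.32) were set apart but lost the call in 4 and 5 of 10 alternatives.

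Marker transcripts of other cell types were also higher on the macrophage array. NK cell markers were higher in 8 of 11 members (median 2.69, percentile 100), with the granzyme gene Gzma at 4.93 and Eomes, a transcription factor of NK and T cells, at 4.17. Platelet and megakaryocyte markers had a median of 2.42 with 5 of 9 higher, B cell markers 1.95 with 8 of 13, plasma cell markers 1.87 with 5 of 8, and the basophil, mast cell and eosinophil group 2.40 with 3 of 5. The NK cell call ended with a floor at the 75th percentile and the platelet call without a floor. T cell (0.85), plasmacytoid dendritic cell (0.98), neutrophil (0.04), dendritic cell (-0.03) and endothelial and stromal markers (0.42) were not set apart, although the plasmacytoid list was under 6 of 10 alternatives, the T cell list under 3 of 9 and the dendritic list under 2 of 10. Further probe sets of genes differing by 2-fold moved the same way in 85.8% of cases, and by 2-fold in 53.6%.

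**Figure D3:**
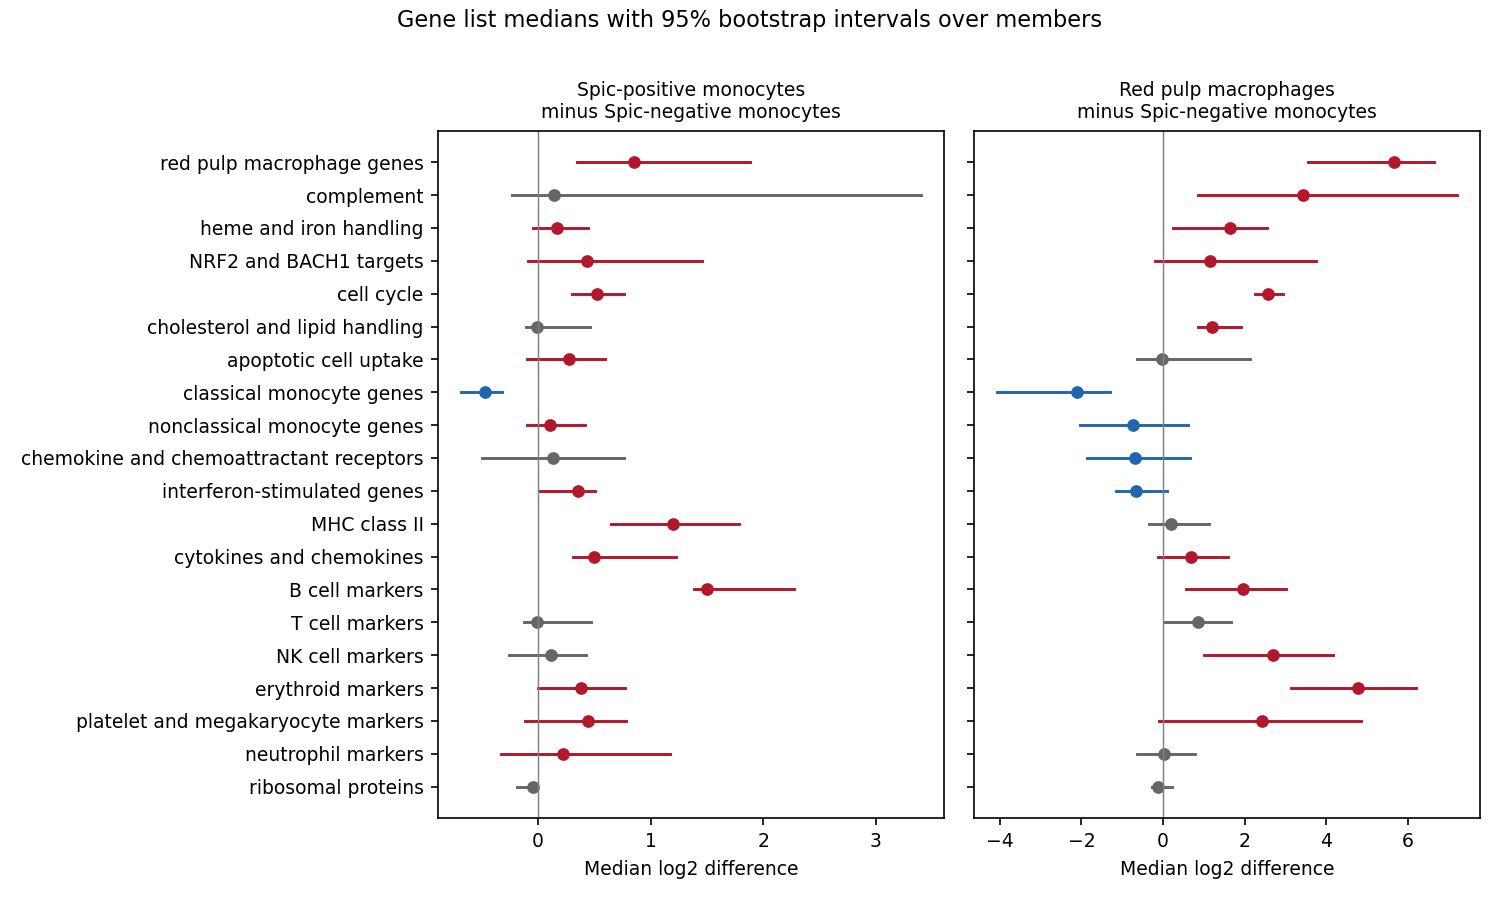
Median log2 difference of 20 of the fixed gene lists (dots) with 95% bootstrap intervals over members (lines), for Spic-positive monocytes and red pulp macrophages, each against Spic-negative monocytes. Lists set apart above matched random lists are red, those set apart below them blue and the others grey. The red pulp macrophage list lay at 0.86 and 5.66, the classical monocyte list at -0.47 and -2.11 and MHC class II at 1.20 and 0.21.

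Against Spic-positive monocytes, red pulp macrophages were higher in Col14a1 (7.85), Hemgn (7.75), Cd163 (7.67), Slc4a1 (7.49), Car2 (7.40), Xist (7.25) and Cd5l (7.21). Slc40a1 was still higher by 4.59 and Hmox1 by 3.12. Lower in macrophages were Ccr2 (-5.03) and F13a1 (-4.56), as against the Spic-negative cells, together with genes that were high in Spic-positive monocytes, among them Ciita (-4.52), Mmp14 (-4.48) and the Ly6 family gene Ly6i (-4.59).

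Counts were 2722 genes higher and 1435 lower at 2-fold, and 893 higher and 252 lower at 4-fold. The remaining named genes upwards were the immunoglobulin gene Ighg3 (6.93), the procollagen protease enhancer gene Pcolce2 (6.43), C6 (6.42), Cmbl (6.42), the C-type lectin gene Clec1b (6.33), the elastase gene Cela1 (6.30), the prostacyclin synthase gene Ptgis (6.16) and Mrap, an accessory protein of melanocortin receptors (6.07). Downwards they were Ifi44l (-6.95), Eif2s3y (-6.25), Ifi202b (-5.70), Gdpd3 (-5.55), Stxbp6 (-5.37), BC018473 (-5.15), Tiam1 (-4.63), Ifit1bl1 (-4.36), the RNA-binding protein gene Celf4 (-4.07) and Mefv, the gene for pyrin (-4.07). Of the 15 genes with the largest differences upwards, only Cd5l, Ighg3, Clec1b and Cela1 were above the floor in Spic-positive monocytes, and of the 15 downwards, only Ccr2, F13a1, Tiam1, Ly6i, Ciita and Mefv were above it in macrophages.

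Red pulp macrophage genes were 2-fold higher in 15 of 16 members (median 3.71, percentile 100), with Maf (0.85) as the exception. Heme and iron genes had a median of 1.48 with 13 of 22 higher and 2 lower, complement genes 3.37 with 8 of 12 higher, cholesterol and lipid genes 1.12 with 12 of 20 higher and cell cycle genes 1.96 with 29 of 30 higher. Heme synthesis genes had a median of 1.37 (percentile 98.6), set apart in 6 of 10 alternatives. NRF2 and BACH1 targets had no shared direction (median -0.11, percentile 26.8), but were set apart with the mean of probe sets, at 0.70: Hmox1 and Slc40a1 were higher in macrophages, whereas Txnrd1 was lower (-1.21) and Gclm differed by -0.20. The erythroid median was 4.24, NK cell markers 2.37, platelet markers 2.90 and plasma cell markers 1.54, while B cell markers differed by -0.14 and were not set apart. The B cell list was set apart upwards with the mean and the median of probe sets, with a median of 1.4 under the latter. The NK cell and platelet calls ended with a floor at the 75th percentile, and the platelet call also without a floor.

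Classical monocyte genes were lower by list, with a median of -2.24, as were nonclassical monocyte genes (-0.70), interferon-stimulated genes (-0.76), chemokine and chemoattractant receptors (-1.06), neutrophil markers (-0.85) and dendritic cell markers (-0.63). Cytokine and chemokine genes had a median of -0.42 with 8 of 29 higher and 11 lower, a call that ended with quantile normalization again and with cyclic loess. MHC class II genes had a median of -0.68 with Cd74 at -1.64, set apart in 5 of 10 alternatives. The other lists were not set apart: apoptotic cell uptake (0.34), lysosome (0.34), oxidative phosphorylation (0.32), glycolysis (0.27), ribosomal proteins (0.04), adhesion (0.15), transcription factors (-0.035), pattern recognition receptors (-0.06), immediate early and heat shock genes (0.01), T cells (0.61), plasmacytoid dendritic cells (0.52), endothelial and stromal cells (0.115) and the basophil group (0.27). Among these, the lysosome list was set apart under 4 of 10 alternatives, transcription factors under 2 of 10 and the basophil group under 1 of 8. Centring the arrays moved the median of all genes in this comparison from 0.10 to 0.23, which the smaller of these medians do not exceed. Further probe sets moved the same way in 80.1% of cases at 2-fold, and by 2-fold in 48.7%.

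Spic-positive monocytes lay between the other populations but close to Spic-negative monocytes for most genes that differed in macrophages. Vcam1, C1qa and Spic stood near or past the midpoint on the log2 scale, while Cd163, Col14a1 and C6 were within 2-fold of the Spic-negative level. So were the erythroid genes Car2 and Slc4a1. All of these genes within 2-fold lay below the floor on both monocyte arrays. Over the 913 genes at least 4-fold higher in macrophages, the median position was 0.119 (interquartile range 0.0013 to 0.268) and 75.03% moved in the direction of macrophages, 193 by at least 2-fold, against 10 that moved the other way by as much. The erythroid genes Hemgn, Slc4a1 and Car2, and Xist, were among these 913, and their source on the macrophage array was not settled. Over the 325 genes at least 4-fold lower in macrophages, the position was 0.177, 82.8% moved the same way and 56 did so by 2-fold, against 3 the other way.

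The Spic-negative array enters both differences, so part of this comes from chance in it. When the monocyte arrays were exchanged at random for each gene, the median position was 0.0715 and at most 0.0918 for the higher genes, and 0.0997 and at most 0.142 for the lower genes. In these exchanges a median of 62.7% of the higher genes moved the same way and at most 67.5%, and 67.5% and at most 75.1% of the lower genes. The exchanges gave at most 156 higher genes moving the same way by 2-fold, against the 193 measured, but up to 57 lower genes, so the 56 measured lay inside their range. Simulated unchanged arrays with noise of 0.40 log2 in each array gave 98.7%, but over 2.48 genes a draw. Those genes passed the selection through noise alone, part of it in the shared array, so their share is no reference for the measured one. Selecting genes against the mean of both monocyte arrays, an alternative chosen after seeing the data, left a median difference of 0.21 toward macrophages over 878 higher genes, of which 64.1% moved that way, and of 0.28 over 262 lower genes, of which 70.2% did. The median position of Spic-positive monocytes, genes higher in macrophages, was then 0.0658, and 0.0621 with 2-fold selection. The median position of Spic-positive monocytes, genes lower in macrophages, was then 0.0924.

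Of the 432 genes 2-fold higher in Spic-positive monocytes, 259 were also 2-fold higher in macrophages, against 84.5 for independent lists and a median of 211 after random exchange. Of the 379 lower genes, 129 were lower in macrophages as well, against 42.9 and 126, so the exchange alone gave nearly as many. Among the 379 lower genes, 164 were at least 2-fold lower in Spic-positive monocytes than on both other arrays, 0 of them at least 4-fold. Of the 432 genes, 123 were at least 2-fold higher in Spic-positive monocytes than on both other arrays, 8 of them at least 4-fold. These 8 were Mmp14, Cxcl11, Ccl5, Ly6i, Cr2, the complement factor B gene Cfb, the immunoglobulin segment Ighv14-2 and Ccr7, of which Cxcl11 and Ighv14-2 were named after their values were seen. Cr2 belongs to the B cell list, of which 11 of 13 members were at least 2-fold higher in Spic-positive than in Spic-negative monocytes. Whether B cells in that sort gave part of these differences was not tested. Cxcl11, a chemokine gene, measured 5.80 in Spic-negative monocytes, 8.75 in Spic-positive monocytes and 5.74 in macrophages, and Cfb measured 7.09, 9.83 and 7.38.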

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

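All tests in this part were chosen after the results were seen. The hybridization controls, unnamed probe sets and globin probe sets were left out of the gene comparisons. The hybridization controls were brighter on the Spic-positive array than on the Spic-negative array by a median of log2 2.16. Among unnamed probe sets above the floor, 9 were at least 4-fold higher and 9 lower in Spic-positive than in Spic-negative monocytes, and 150 were higher and 182 lower in red pulp macrophages.

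Globin transcripts, the most abundant of red cell precursors, are measured by probe sets shared between near-identical genes. A probe set of the beta-globin genes was higher in Spic-positive than in Spic-negative monocytes by log2 1.76, and 3 probe sets of the alpha-globin genes by 4.04, 4.71 and 5.13. On the macrophage array the beta-globin probe set was at 13.98 and the brightest alpha-globin probe set at 14.35. On the Spic-positive array the alpha-globin probe sets lay at percentiles of 76.60 to 98.40, while Slc4a1 measured 3.83 and Hemgn 2.60, both below the floor. The median of the erythroid list was higher by 0.38 in Spic-positive than in Spic-negative monocytes, a call that ended under 8 of 10 alternatives, with a median as low as 0.18, and the source of the globin signal on that array was not tested.

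Erythroid, NK cell and platelet genes were high on the macrophage array. The test of a lower share of the sorted cell type took it that other types let in alike would raise their markers alike. The medians of 11 lists of other cell types spanned log2 4.81, from -0.03 for dendritic cells to 4.78 for erythroid cells. The markers started from unequal levels, however: on the Spic-negative array Slc4a1 of the erythroid list measured 3.86 and Itgax of the dendritic list 7.27. An even admixture can therefore give unequal medians too, so the span does not decide this question. Other cell types let in unevenly would also give unequal medians, so a lower share of the sorted cell type was not excluded. Erythroid cells or their RNA, bound to or taken up by the macrophages, may account for the erythroid part. The globin probe sets had a median percentile of 99.97 on the macrophage array, with 1 of 4 outside the top 1% at 97.99, and no sort step was directed at erythroid cells. The red cell gene Slc4a1 measured 11.32 there, but it is part of the pattern to be explained and so is no separate support. Whether the RNA came from attached cells, engulfed cells or free RNA, and the source of the NK cell and platelet transcripts, were not tested. Macrophages that themselves transcribe such genes were not tested either.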

How the results depend on the processing

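The selection against the mean of both monocyte arrays and the counts without X and Y genes were chosen after seeing the data. Counts followed the threshold, by construction. At 1.5-fold they were 1287 genes higher and 1563 lower in Spic-positive against Spic-negative monocytes, 3656 and 2732 in macrophages against Spic-negative monocytes, and 4129 and 3031 in macrophages against Spic-positive monocytes. At 3-fold they were 156 and 45, 1351 and 604, and 1424 and 493. With the mean of all probe sets 237 genes were 2-fold lower in Spic-positive monocytes, and with their median 10 were 4-fold lower. A floor at the 75th percentile, which leaves fewer genes, gave 249 genes 2-fold higher in Spic-positive monocytes and 943 genes 2-fold lower in macrophages against Spic-positive monocytes. The other 104 of 120 counts under alternatives stayed within 1.5 times. The median position of Spic-positive monocytes, genes higher in macrophages, was 0.0621 with 2-fold selection and 0.0658 with selection against the mean of both monocyte arrays. The median position of Spic-positive monocytes, genes lower in macrophages, was 0.0924 with the latter. That selection weighs both monocyte arrays alike, but the Spic-negative array still enters it and the position. The other 21 of 24 positions were within 0.05 of the main value.

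The median of dendritic cell markers, Spic-positive monocytes against Spic-negative monocytes, turned to -0.018 without Ccr7, without a floor and with a floor at the 75th percentile. Igkv9-120 turned to 0.49 without probe sets ending in _x_at or _s_at and 1810014B01Rik to 0.12 with the median of its probe sets. Except for the list without Ccr7, the cause was not tested. Of 1005 list percentiles under alternatives, 908 kept their call, and 897 of 903 list medians stayed inside the main 95% interval over members, which is wide for short lists and includes 0 for some. Of 716 values of named genes, 647 stayed within the median gap between probe sets of a gene. Signal over background limits genes under log2 5.02, where differences are uncertain.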

Other observations

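The tests of a single macrophage share, of chance in the shared array and of the sex of the mice were chosen after the results were seen, and that of a compressed range before. Members of the neutrophil list, picked here after their values were seen, differed in direction between the monocyte arrays. Of 16 members, 5 were at least 2-fold higher and 1 lower, with a median of 0.22. That call ended without the member of largest difference. Mpo, Prtn3 and Ctsg, which encode proteins of primary granules, were higher than in Spic-negative monocytes by log2 2.86, 1.69 and 2.05, and the stem cell factor receptor gene Kit, from another list, by 2.16. Fcnb, also of the neutrophil list, was higher by 1.46. Members of that list that were lower or differed little included Mmp8 at -0.95, Mmp9 at -1.10, Csf3r at -0.49 and S100a9 at 0.02. Spib, an Ets factor related to Spic and a member of the plasmacytoid dendritic cell list, was higher by 2.46. On the same array 11 of 13 B cell markers were at least 2-fold higher. Bhlhe40, a regulator of macrophage growth, was higher by 1.38.

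Genes higher in macrophages were raised in Spic-positive monocytes. Red pulp macrophages in the Spic-positive sort could give this. The best single share, 2.75%, left 19.7% of 913 genes at least 2-fold off, 113 above and 67 below, with a second probe set on the same side for 36 of 42. Second probe sets share the RNA and cover probe set error only. How many genes array noise alone would put 2-fold off was not estimated. Of all 12375 genes, 3.49% were 2-fold higher and 3.06% lower in Spic-positive than in Spic-negative monocytes. The misses argue against macrophages as the only source for all 913 genes only as far as noise did not cause them, and leave a part open. The erythroid genes Hemgn, Slc4a1 and Car2, and Xist, were among the genes below the fit, and the immunoglobulin segment Iglv1 among those above. Such genes may miss the fit for reasons other than the share of macrophages, so macrophages in the sort beside other cells were not excluded. Chance in the shared Spic-negative array, independent between genes, gave at most 67.5% of genes moving the same way, and 75.03% did, which argues against such chance as the whole source, while deviations shared by the genes of an array stay open. A compressed range on the Spic-positive array, whose hybridization controls also differed, cannot be told apart: genes of the same Spic-negative level were raised by 0.15, and the excess of 0.14 over them met the criterion set beforehand, over 0.1 with an interval above 0, but its interval of 0.08 to 0.18 reaches below 0.1, so the bound was not passed by more than the spread. A partial macrophage programme in these monocytes stays among the open explanations.

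Xist was high and Y-linked genes were low on the macrophage array, with Xist at 4.63, 4.70 and 11.95 in Spic-negative monocytes, Spic-positive monocytes and macrophages, Eif2s3y at 10.10, 9.56 and 3.31 and Kdm5d at 7.25, 6.49 and 2.52. Macrophages from female mice and monocytes from male mice could be the source, but this cannot be told apart from other sources: of 6 Y-linked genes above the floor on a monocyte array, 5 lay below it in macrophages, and Sry, named after its values were seen, stayed above at 5.50 against 5.77 and 5.58. All but Eif2s3y and Kdm5d lay within 2-fold of the floor on a monocyte array, and Sry did so on each array, so it neither excludes nor bears out the explanation. A later form of the test, limited to Eif2s3y and Kdm5d, was dropped because these genes had prompted the explanation. The labels used here give no sex and no strain background, so neither can be separated from cell type for differences between the macrophage and monocyte arrays.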
